A study of Mus musculus with 6 samples.

How the data were processed

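The data are gene-level RNA-seq values from pancreatic islets of 6 male mice on a high fat diet, 3 with an inducible endothelial deletion of Ern1 and 3 floxed littermates. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were sequenced as paired reads of 150 bases on a DNBSEQ-T7 instrument. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used with the mm10 build, and versions are not given in the sources used here. The authors deposited estimated counts per gene, not normalized, with gene symbols and Entrez identifiers. Of the 11106 genes listed, 1422 (12.8%) had a value that was not whole in at least 1 library, and the source of these decimals was not tested. The table lists an incomplete set of genes: 11076 are protein coding and 0 are mitochondrially encoded, and the rule behind it is not given in the sources used here. The counting rule and the use of strand are not given either. All 6 value columns belonged to the 6 samples. Entrez identifiers were matched to a RefSeq gene table of GRCm38.p6, the same assembly as mm10, for 11090 genes, and 16 did not match. Coordinates come from that table.

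Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 11080, and libraries were scaled by TMM (factors from 0.924 to 1.11). Groups were compared with edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16 in R 4.3.3) with no covariate, p-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. Log2 fold changes are knockout against floxed, their standard errors come from the quasi-likelihood F statistic, and intervals are at 95%. CPM are scaled by TMM unless they are summed as shares of counts, which use library totals. Log2 CPM carry a prior count of 2. Total counts ran from 18470720 to 18957444 per library, which puts 1 CPM at about 19 counts. The replicate libraries differed by more than counting noise (chi-square per gene of at least 20.2 for every library against the closest of its own group), so each counted as 1 sample. No paired or blocked fit was run, since the groups share no animal numbers and no litter, batch or pairing is given in the sources used here. Differences between litters or batches therefore cannot be told apart from the groups.

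Before the data were examined, 32 gene lists for cell types, pathways and tissue handling were fixed, along with the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members (27) were tested with camera at a preset correlation of 0.01 (limma 3.58.1) and adjusted over the 27 lists. With an estimated correlation 0 lists passed (smallest adjusted p = 0.509; 2 lists at an unadjusted p below 0.05), and with fry, which tests whether the genes of a list move one way on balance, 0 passed (smallest adjusted p = 0.170), a count that held with all 6 libraries and not without floxed 8. For each list the passing genes are counted over all genes tested and adjusted over the list alone. The adjustment over the list alone does not correct for the number of lists. Passes by it are easily reached here, since 1986 of the 11080 tested genes had an unadjusted edgeR p below 0.05. Shares of cell type markers and the list means were compared with exact two-sided permutation tests, which cannot go below p = 0.10 with 3 against 3.

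The rule for named genes took Ern1, Thbs1, Xbp1, Ins1, Ins2, Gcg, Sst, Pecam1, Cdh5, Kdr and Vegfa. It added the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out genes known only by model numbers. Where fewer than 10 passed, the genes with the smallest unadjusted p followed. In each list up to 4 members with the smallest unadjusted p could be named. Which of these list members the text names was decided after their values were seen, and the result of 1 of them is not reported here. Overlaps between the exons of the genes named apart from the lists and those of other genes were looked up in GENCODE annotation of the same build.

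The fit and the list test were tested on simulated data, drawn from the observed means, dispersions and library sizes of this comparison. After the expression filter 11077 simulated genes were tested. Of 100 genes changed by a log2 value of 1, 88% were recovered, of 100 changed by 2, 99% were, and 14 of the 201 genes called had not been changed. The list of changed genes was called and 0 of 20 unchanged lists were. Each gene was drawn independently, so this could not show how the list test behaves with correlated genes. In the data the estimated correlation was 0.95 for immediate early and heat shock genes and 0.52 for endothelial markers.

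Alternatives fixed beforehand were RLE scaling, library totals, no expression filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, no robust fit, acinar genes removed before scaling, the mean log2 CPM of acinar genes as a covariate, a threshold of 0.10, and each library left out. Added after seeing the data were the mean log2 CPM of immediate early and heat shock genes as a covariate, a per-library loess correction for transcript length (98.0% of genes had a length), knockout 12 and floxed 8 left out together, a test for called genes lying close together on a chromosome, and a camera test of 623 Reactome sets of 15 to 300 genes taken from the fgsea package (1.28.0).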

Results

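RNA-seq read counts were examined for pancreatic islets of 6 male mice, 3 with an endothelial cell deletion of Ern1 (knockout 11, 12 and 13) and 3 floxed littermates that kept the gene (floxed 8, 18 and 19). Ern1 encodes IRE1α, a sensor of endoplasmic reticulum stress whose RNase splices Xbp1 mRNA and degrades selected other mRNAs. The floxed gene was removed with a tamoxifen-inducible Cre under the VE-cadherin promoter, which is active in endothelial cells, and both groups received 2 mg tamoxifen on 5 days at 4 weeks of age. From the age of 8 weeks all 6 mice ate a diet with 60% of its energy from fat, and this lasted 16 weeks. Total counts ran from 18470720 to 18957444 per library, over 11106 genes. Ins1 and Ins2, the insulin genes, together held between 28.2% (knockout 12) and 43.4% (floxed 18) of the counts. The libraries are separately numbered mice, so the spread within a group is a spread between animals. The study asked how endothelial IRE1α supports the growth of vessels within islets under excess nutrition, and its title names the decay of thrombospondin-1 mRNA, so Thbs1 and the vascular genes are given before the other groups.

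Ern1 itself did not differ in these whole islets. It stood at 41.9, 36.0 and 46.8 CPM (counts scaled to library size) in knockout 11, 12 and 13 and at 30.1, 44.6 and 46.0 CPM in floxed 8, 18 and 19, a log2 fold change of 0.05 with a standard error of 0.17 and an adjusted p of 0.920 (edgeR quasi-likelihood test, Benjamini-Hochberg). The gene lies on chromosome 11 from 106397620 to 106487796 (GRCm38). Endothelial cells are a small part of an islet, the other cells keep the gene, and the counts cover the whole gene, so this value checks the genotype labels very little. Xbp1, the mRNA that IRE1α splices, stood at 272 ± 14.3 CPM in knockout and 242 ± 31.0 CPM in floxed islets (SD, n = 3 each) as a total over both splice forms.

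Thbs1, which encodes the anti-angiogenic matrix protein thrombospondin-1, stood at 119 ± 61.3 CPM in knockout and 29.3 ± 4.76 CPM in floxed islets (SD, n = 3 each), a 4.05-fold difference. The lowest knockout library was 2.18-fold above the highest floxed library, with 75.5, 189 and 91.8 CPM in knockout 11, 12 and 13 against 27.8, 25.6 and 34.7 CPM in floxed 8, 18 and 19. The log2 fold change was 2.02 with a standard error of 0.39 and a 95% interval from 1.04 to 3.00. Its unadjusted p was 0.00273 and its adjusted p over all genes was 0.0948 in the edgeR quasi-likelihood test, so it missed the threshold of 0.05. An exact two-sided permutation test gave p = 0.10, the smallest value that 3 against 3 libraries allow. Without knockout 12, which had the highest value, the log2 fold change was 1.51 and the edgeR adjusted p was 0.0365, and the adjusted p ranged from 2.8e-04 to 0.638 over all the alternatives. Thbs1 lies on chromosome 2 from 118111876 to 118127133, and an annotated gene on the opposite strand, Gm29233, overlaps its exons. Strand use is not given in the sources used here, so reads of that gene cannot be told apart from its own.

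Of 9 measured genes fixed as substrates of IRE1-dependent mRNA decay, 2 passed when adjusted over the list alone, Thbs1 and the scavenger receptor gene Scara3, and 0 passed over all genes tested. The study's title names the decay of Thbs1 mRNA, so the place of Thbs1 in this list was not chosen apart from the study. Scara3 stood at 3.65, 6.85 and 3.67 CPM in knockout 11, 12 and 13 and at 1.62, 1.25 and 1.63 CPM in floxed 8, 18 and 19 (log2 fold change 1.66, standard error 0.30, edgeR adjusted p = 0.0596). Col6a1, another member, was at 34.1 CPM in knockout 12 and between 4.42 and 6.41 CPM in the other libraries, and Tapbp, which loads peptides onto MHC class I, had a log2 fold change of -0.26 (edgeR adjusted p = 0.218). The list as a whole was not called by camera (adjusted p = 0.202; median log2 fold change 0.01), and it was called without knockout 13 (adjusted p = 0.0203).

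The list of anti-angiogenic genes was called higher in knockout islets with all 6 libraries, with a median that depended on knockout 12. Thbs1, which the study's title names, is a member, so its place in this list too was not chosen apart from the study. Adamts1, a secreted protease that inhibits vessel growth, rose from 8.54 ± 3.23 CPM in floxed to 24.7 ± 1.33 CPM in knockout islets (SD, n = 3 each), a log2 fold change of 1.54 with a standard error of 0.23 and an edgeR adjusted p of 0.0483. Of the 8 measured anti-angiogenic genes, 6 had positive values, 1 passed over all genes tested and 2, Adamts1 and Thbs1, when adjusted over the list alone. Camera called the list higher (median log2 fold change 0.78, adjusted p = 0.0160), a call lost with limma-voom (adjusted p = 0.0750; 0.128 with quality weights), with the acinar level (median 0.47, adjusted p = 0.199) or the immediate early level (median 0.42, 0.132) as a covariate, and with an estimated correlation (adjusted p = 0.509 with an estimated correlation). Without knockout 12 the median was 0.0508 (adjusted p = 0.0216), and without both knockout 12 and floxed 8 it was -0.0511 (adjusted p = 0.00905). The chemokine gene Cxcl10 had a log2 fold change of 1.38 and the semaphorin gene Sema3f one of -0.21, with edgeR adjusted p of 0.5004 and 0.306. The list of thrombospondin-1 receptors and TGF-beta targets was also called higher (median log2 fold change 0.28, adjusted p = 0.0404). Its call ended without knockout 12 (median 0.14, adjusted p = 0.231), with limma-voom (0.0547; 0.0506 with quality weights), with the acinar (0.455) or immediate early covariate (0.452) and with the length correction (0.0596), while the median kept its size in the last 3 of these (0.28, 0.31 and 0.25). Without knockout 11 the median was 0.42, and the list stood at adjusted p = 0.633 with an estimated correlation. Of its 10 measured members, 0 passed over all genes tested and 1, Skil, a repressor of SMAD signalling induced by TGF-beta, when adjusted over the list alone. Skil had 30.5 ± 5.39 CPM in knockout and 16.3 ± 4.84 CPM in floxed islets (SD, n = 3 each), and Smad7, another TGF-beta target, had a log2 fold change of 0.69. The matrix gene Ccn1 was at 145, 258 and 133 CPM in knockout 11, 12 and 13, at 72.8 CPM in floxed 8, and at 13.7 and 20.4 CPM in floxed 18 and 19. These 3 genes shrank more than the list median. Over all the alternatives the lowest log2 fold changes of Skil, Smad7 and Ccn1 were 0.35, 0.15 and 0.48. With single libraries left out the lowest were 0.74, 0.52 and 1.94.

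With all 6 libraries, pro-angiogenic factors and receptors showed no common direction. Without floxed 8 the median log2 fold change was -0.15, and 2 members were called higher and 4 lower over all genes tested. Camera then gave an adjusted p of 0.443 and fry one of 0.0323. The values that follow are from all 6 libraries. Of 14 measured members 0 passed by either adjustment, 8 had positive and 6 negative values, and camera gave an adjusted p of 0.868, with a downward direction beside a median log2 fold change of 0.02. Vegfa, the main vessel growth factor of islets, stood at 360 ± 14.2 CPM in knockout and 313 ± 59.0 CPM in floxed islets (SD, n = 3 each). Vegfb had a log2 fold change of -0.32 and Pdgfa one of 0.35, with edgeR adjusted p of 0.221 and 0.193. The 12 measured basement membrane genes had a median log2 fold change of 0.02 (camera adjusted p = 0.866), and the 17 hypoxia response genes one of 0.06 (adjusted p = 0.689), with 0 members of either list passing by either adjustment. The basement membrane list was called higher by camera with the acinar or immediate early covariate (adjusted p = 0.0387 and 0.0247) and lower without both knockout 12 and floxed 8 (adjusted p = 0.0148). Without floxed 8 the hypoxia list had a median of 0.12, with 0 members called higher and 2 lower over all genes tested. Its adjusted p was then 0.772 with camera and 0.00575 with fry.

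**Figure D1:**
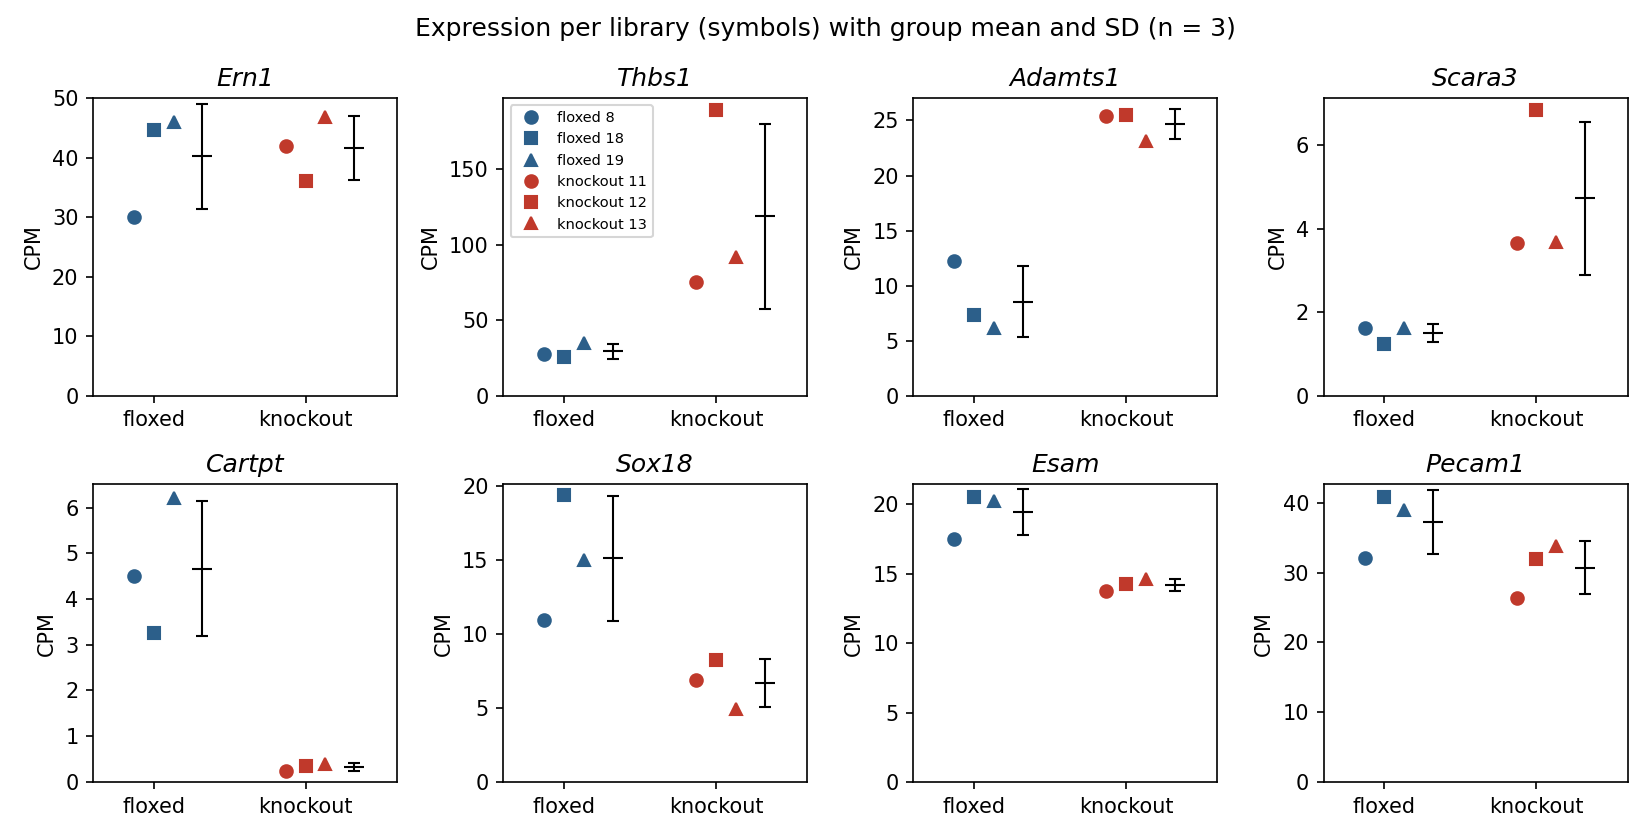
Expression in CPM (vertical axis, starting at 0) of 8 genes in each library, with floxed islets in blue and knockout islets in red; symbols are single mice, and the bars give the mean and SD (n = 3). Thbs1 lies between 25.6 and 34.7 CPM in the floxed libraries and between 75.5 and 189 CPM in the knockout libraries, while Ern1 overlaps between the groups.

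Endothelial cell markers were lower in knockout islets, by a median log2 fold change of -0.28 over 22 measured genes, of which 21 had negative values. Sox18, an endothelial transcription factor, stood at 6.69 ± 1.65 CPM in knockout and 15.1 ± 4.24 CPM in floxed islets, and Esam, an endothelial adhesion molecule, at 14.2 ± 0.437 and 19.4 ± 1.66 CPM (SD, n = 3 each). Sox18, Esam, Egfl7 and Emcn passed when adjusted over the list alone, and 0 members passed over all genes tested. The widely used markers were closer together: Pecam1 had a log2 fold change of -0.28, Cdh5 one of -0.13 and Kdr one of -0.16, with edgeR adjusted p of 0.292, 0.787 and 0.717. Camera called the endothelial list lower (adjusted p = 4.6e-06), and the adjusted p was 0.633 with an estimated correlation. With the acinar marker level or the immediate early level as a covariate the list was no longer called (medians 0.0372 and 0.0530, camera adjusted p = 0.651 and 0.477). Floxed 8 stood with the knockout libraries: the list mean was 3.97, 3.88 and 3.94 log2 CPM in knockout 11, 12 and 13, 3.94 in floxed 8, and 4.38 in both floxed 18 and floxed 19. These markers held 0.0599 ± 0.00130% of counts in knockout and 0.0790 ± 0.0183% in floxed islets (SD, n = 3 each; exact permutation p = 0.40). Without floxed 8, 14 of the 22 markers fell by the edgeR test over all genes, among them Pecam1 and Kdr (log2 fold changes -0.38 and -0.37).

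Markers of pericytes and smooth muscle, the cells that wrap vessels, were lower as well, in 10 of 10 measured genes (median log2 fold change -0.33). Myl9 had a log2 fold change of -0.75 and Rgs5 one of -0.40, and these 2 genes passed when adjusted over the list alone, with 0 over all genes tested. Camera gave an adjusted p of 6.2e-04, which was 0.509 with an estimated correlation, 0.756 with the acinar marker level (median -0.0164), and 0.703 with the immediate early level as a covariate (median -0.0136). Floxed 8 lay nearer to the knockout libraries in the list mean, with 2.80, 2.74 and 2.59 log2 CPM in knockout 11, 12 and 13, 2.87 in floxed 8, and 3.21 and 3.17 in floxed 18 and 19, and in 5 of the 10 genes. Without floxed 8, 3 of these genes fell over all genes tested.

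**Figure D2:**
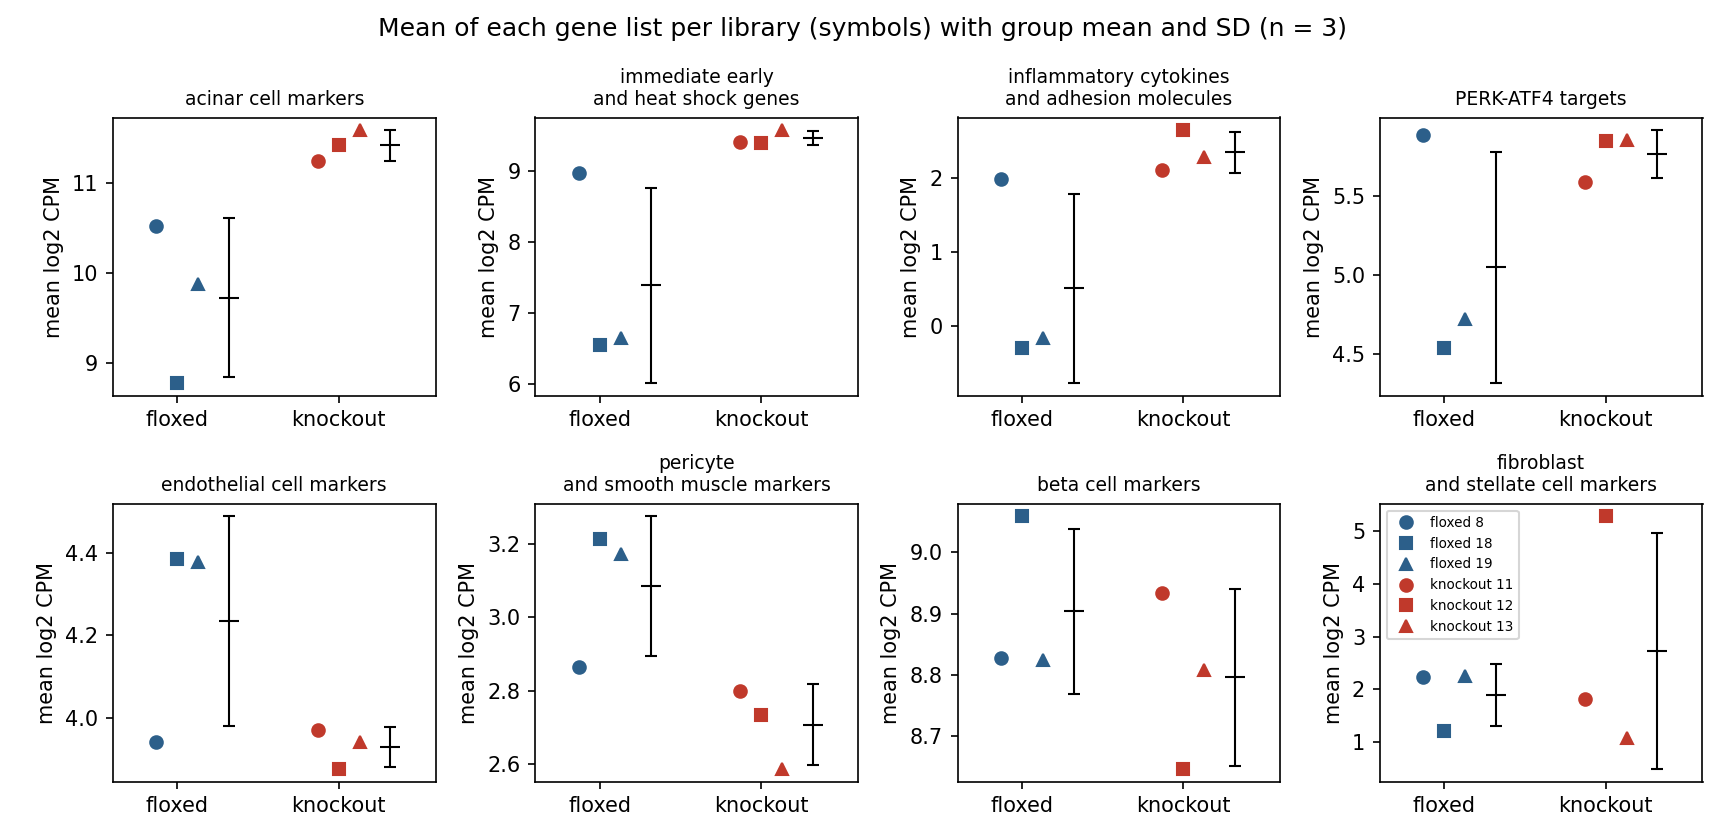
Mean log2 CPM of 8 gene lists (vertical axis, not starting at 0) in each library, with floxed islets in blue and knockout islets in red; symbols are single mice, and the bars give the mean and SD (n = 3). Floxed 8 lies at 8.98 for immediate early and heat shock genes, beside 9.39 to 9.57 in the knockout libraries and 6.55 and 6.65 in floxed 18 and 19.

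Across all genes, 45 of 11080 tested differed between the groups, 38 higher and 7 lower in knockout islets (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). The largest rises were in Prss1, a trypsinogen (log2 fold change 4.97), the keratin gene Krt23 (3.27), the serine protease gene Habp2 (2.54) and Serpini2, a pancreatic serine protease inhibitor (2.29). Further rises were in the AP-1 factor Fosl2 (1.80), the MAP kinase phosphatase Dusp4 (1.59), the matrix protein vitronectin, Vtn (1.56), Adamts1, the secreted chaperone clusterin, Clu (1.47), and Pdlim1 (1.47). Serpini2 went from 14.6 ± 3.97 to 71.1 ± 11.1 CPM (SD, n = 3 each; adjusted p = 0.00963), and Clu from 189 ± 56.1 to 525 ± 77.6 CPM (adjusted p = 0.0463). The counts of Prss1, which belongs to a family of near-identical trypsinogens, and of Habp2 were not whole numbers and are uncertain, and Habp2 also overlaps an opposite-strand gene.

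The largest fall was in Cartpt, which encodes the neuroendocrine peptide precursor CART and went from 4.66 ± 1.48 CPM in floxed to 0.324 ± 0.0848 CPM in knockout islets (SD, n = 3 each), a log2 fold change of -3.81 with a standard error of 0.36 (edgeR adjusted p = 0.00840). Cartpt was low in all 3 knockout libraries and above 3.2 CPM in all 3 floxed libraries, floxed 8 included. The meiotic cohesin gene Rec8 fell by 2.56 on the log2 scale and Ppp1r3b, which targets a phosphatase to glycogen, by 1.87. Iqgap2, the interferon-inducible nucleotide kinase gene Cmpk2 and the DNA polymerase delta subunit gene Pold2 fell by 1.01, 0.73 and 0.64. Isg20, Rab2b, Yipf2 and Ly6a had the smallest p-values among further genes with lower values and did not pass, with log2 fold changes of -0.56, -0.67, -0.50 and -0.65 and edgeR adjusted p from 0.0595 to 0.0647. Exons of Rab2b and Yipf2 overlap those of other genes. The count of 45 genes moved with each left-out library: it was 0 without knockout 11, 0 without knockout 13, 8 without knockout 12, 18 without floxed 18, 16 without floxed 19 and 1584 (952 higher, 632 lower) without floxed 8. Of all tested genes, 1986 had an unadjusted edgeR p below 0.05, and 24.3% showed no overlap between the groups, against 10% by chance.

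**Figure D3:**
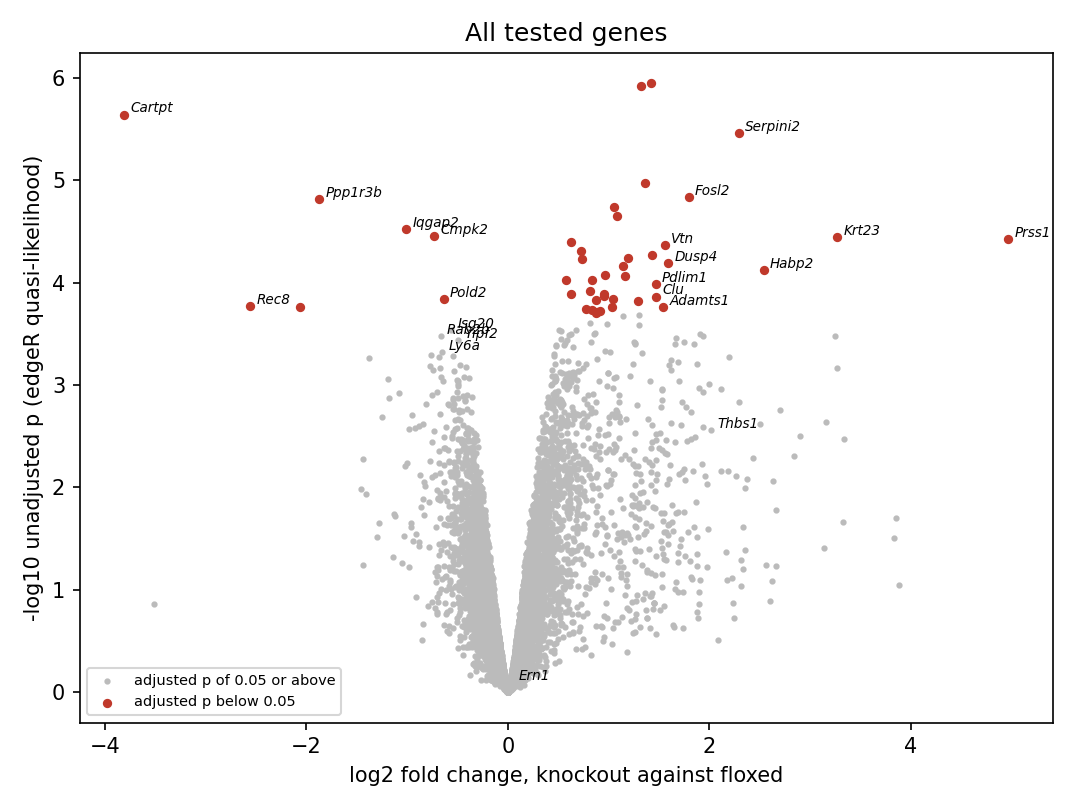
Log2 fold change of knockout against floxed islets (horizontal axis) and -log10 of the unadjusted edgeR p (vertical axis) for all 11080 tested genes, with the 45 genes past an adjusted p of 0.05 in red. Thbs1 and Ern1 are grey, and Cartpt is the lowest of the red points on the horizontal axis.

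Exocrine markers, taken as a share of counts or as a list mean, were higher in every knockout library than in any floxed library. Single acinar members overlapped between the groups. The 22 acinar markers, digestive enzymes and their transcription factors, held 16.4 ± 2.77% of all counts in knockout and 6.06 ± 3.01% in floxed islets (SD, n = 3 each; exact permutation p = 0.10, the smallest possible). All 22 had positive values, with 20 passing when adjusted over the list alone and 0 over all genes tested. Pnliprp1, a pancreatic lipase family gene, stood at 5111 ± 1075 CPM in knockout and 1278 ± 658 CPM in floxed islets (SD, n = 3 each), Cpb1 had a log2 fold change of 1.52, and the acinar transcription factor genes Rbpjl and Ptf1a had values of 2.30 and 2.70. Camera called the list higher (adjusted p = 2.1e-23; 0.509 with an estimated correlation). The 7 measured ductal markers were also called higher (median log2 fold change 0.83, adjusted p = 3.0e-04; 0.509 with an estimated correlation), with 3 passing when adjusted over the list alone, Krt19, Muc1 and Krt18, and 0 over all genes tested. The ductal list was not called with the immediate early level (median 0.16, adjusted p = 0.132) or the acinar level (median 0.0757, 0.443) as a covariate, and with the acinar covariate 0 genes passed the edgeR test in the whole table, where 973 had an unadjusted p below 0.05. All of the 45 genes called without a covariate kept their sign there, with Cartpt at -4.40, Dusp4 at 2.06, Serpini2 at 1.62 and Adamts1 at 0.98 (edgeR adjusted p from 0.0586 to 0.549). Other called genes shrank more in some alternative. Over all the alternatives the lowest log2 fold changes of Krt23, Habp2 and Clu were 1.57, 1.11 and 0.66.

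Endocrine markers were not called by camera. The 20 beta cell markers had a median log2 fold change of -0.13 (adjusted p = 0.0962), the 8 alpha cell markers -0.20 (adjusted p = 0.310) and the 6 delta and PP cell markers -0.26 (adjusted p = 0.350), with 0 members passing by either adjustment. The beta list was called lower without knockout 11 (adjusted p = 0.0406) and without floxed 19 (adjusted p = 0.0325). The alpha list and the delta and PP list were called lower with the acinar covariate (adjusted p = 0.00920 and 0.0190) and with the immediate early covariate (5.5e-04 and 2.9e-04). Without floxed 8, the library with the highest mean of both lists, their medians were 0.11 and -0.00897, and neither was called (adjusted p = 0.917 for both). Beta cell markers held 34.4 ± 4.74% of counts in knockout and 45.3 ± 1.89% in floxed islets (SD, n = 3 each; exact permutation p = 0.10). Ins1 had a log2 fold change of -0.33, Ins2 one of -0.30, glucagon, Gcg, one of -0.21 and somatostatin, Sst, one of -0.36, with edgeR adjusted p from 0.507 to 0.814. The share of alpha cell markers was 3.18% in floxed 8 and between 1.67% and 2.05% in the other libraries. For delta and PP cell markers the means were 0.642 ± 0.0565% in knockout and 0.893 ± 0.214% in floxed islets (SD, n = 3 each; exact permutation p = 0.20).

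Stromal genes stood apart in knockout 12. Its fibroblast and stellate cell markers averaged 5.29 log2 CPM, against 1.08 to 2.25 in the other libraries, and the collagen genes Col1a1 and Col3a1 were at 44.7 and 70.6 CPM there and at no more than 4.79 and 10.2 CPM elsewhere. Lum, a matrix proteoglycan gene, was at 16.1 CPM there and at no more than 1.27 CPM elsewhere. This was also the library with the highest Thbs1. Across groups the list of 5 measured genes was not called (adjusted p = 0.228), nor were the 11 tested macrophage markers (adjusted p = 0.448), whose mean was 3.73 log2 CPM in knockout 12 and 2.07 to 2.57 elsewhere. The macrophage list was called lower without knockout 12 (adjusted p = 0.01004), and without knockout 13 the fibroblast list (adjusted p = 0.00208) and the macrophage list (adjusted p = 0.0203) were both called higher. With fewer than 5 measured genes, 5 lists were not tested: the 4 red blood cell genes had a median log2 fold change of -0.65, 3 adipocyte genes -0.06, 3 Schwann cell genes -0.00481 and 1 lymphocyte gene 0.23, and 0 of 13 mitochondrially encoded genes were listed.

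Immediate early and heat shock genes, which respond within minutes to hours to stress, were higher in knockout islets as a group (15 of 15 with positive values, median log2 fold change 1.55). Jun, an AP-1 subunit, was at 2485, 2285 and 2607 CPM in knockout 11, 12 and 13, at 1409 CPM in floxed 8, and at 294 and 301 CPM in floxed 18 and 19. The chaperone gene Hsph1 had 326 ± 73.9 CPM in knockout and 98.9 ± 74.5 CPM in floxed islets (SD, n = 3 each). Ier3 and Btg2, which are induced by many stresses, had log2 fold changes of 1.27 and 1.31. Camera called the list (adjusted p = 7.0e-11; 0.570 with an estimated correlation; 0.751 with the acinar covariate), while 0 members passed by either adjustment because the floxed libraries were far apart. Without floxed 8, all 15 rose over all genes tested (median log2 fold change 2.73). The acinar list mean also placed floxed 8 nearest to the knockout libraries, with 11.2, 11.4 and 11.6 log2 CPM in knockout 11, 12 and 13, 10.5 in floxed 8, and 8.78 and 9.88 in floxed 18 and 19.

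Inflammatory cytokine and adhesion genes likewise parted the knockout libraries and floxed 8 from floxed 18 and 19. Their list mean was 2.10, 2.64 and 2.28 log2 CPM in knockout 11, 12 and 13, 1.98 in floxed 8, and -0.31 and -0.16 in floxed 18 and 19. The median log2 fold change over 11 tested genes was 1.42 (camera adjusted p = 4.5e-06; 0.570 with an estimated correlation), and 2, the adhesion molecule Icam1 and the chemokine Cxcl1, passed when adjusted over the list alone, with 0 over all genes tested. With the acinar or immediate early covariate the inflammatory list was not called (medians -1.01 and -0.00244, adjusted p = 0.385 and 0.706), and without floxed 8 its median was 2.61. Tnfaip3, an inhibitor of NF-kB signalling, was at 36.2, 37.6 and 85.4 CPM in knockout 11, 12 and 13, at 25.4 CPM in floxed 8, and at 3.99 and 3.26 CPM in floxed 18 and 19. Targets of PERK and ATF4, the arm of the stress response that raises amino acid synthesis, were called higher too (19 genes, median log2 fold change 0.27, adjusted p = 0.0234; 0.693 with an estimated correlation). Their list mean was highest in a floxed library, with 5.89 log2 CPM in floxed 8, 5.59, 5.85 and 5.86 in knockout 11, 12 and 13, and 4.53 and 4.72 in floxed 18 and 19 (exact permutation p = 0.40). Of these genes, 0 passed by either adjustment. Phgdh, the entry enzyme of serine synthesis, had a log2 fold change of 0.80, and Ddit3, the stress factor CHOP, one of 1.38 (edgeR adjusted p = 0.310). The PERK-ATF4 call ended without knockout 12, floxed 18 or floxed 19 (adjusted p = 0.0528, 0.0861 and 0.112), and the median was 0.64 without floxed 8, 0.0833 without floxed 18 and 0.0835 without floxed 19. It turned downward with the acinar covariate (adjusted p = 8.1e-04) and with the immediate early covariate (adjusted p = 5.5e-04).

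Targets of IRE1 and XBP1 and chaperones of the endoplasmic reticulum went both ways. The chaperone gene Hspa5 stood at 3409 ± 413 CPM in knockout and 1589 ± 578 CPM in floxed islets, and Herpud1, a factor of protein degradation at the endoplasmic reticulum, at 819 ± 213 and 333 ± 186 CPM (SD, n = 3 each). Floxed 8 had 2256 and 547 CPM of these genes, above floxed 18 (1228 and 208 CPM) and floxed 19 (1283 and 243 CPM). The log2 fold changes of Hspa5 and Herpud1 were 1.10 and 1.30 (edgeR adjusted p = 0.103 and 0.174). Over all the alternatives the lowest were 0.33 and 0.05. Pdia6 and the translocon gene Sec61a1 had log2 fold changes of -0.51 and -0.41, and 18 of the 24 members had negative values. The median was -0.17, camera did not call the list (adjusted p = 0.0767), and 0 members passed by either adjustment. The list was called lower with limma-voom (adjusted p = 0.0315; 0.00724 with quality weights) and without floxed 8 (0.0249), knockout 12 (0.0423), knockout 13 (0.0254) or both knockout 12 and floxed 8 (0.00641).

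Among metabolic and secretory genes, oxidative phosphorylation was called lower (24 genes, 21 with negative values, median log2 fold change -0.04, adjusted p = 0.0160; 0.693 with an estimated correlation). Ndufa4 and Ndufa1, subunits of the respiratory chain, had log2 fold changes of -0.88 and -0.41, and 0 members passed by either adjustment. The median was -0.0988 without knockout 11 and -0.0884 without floxed 18. The call ended without floxed 8 (median -0.0292, adjusted p = 0.204), without knockout 12 (0.0528), without both knockout 12 and floxed 8 (0.315), with limma-voom with quality weights (0.0634) and after a correction for transcript length (0.244). For each library, transcript length was ranked against the deviation of each gene's log2 CPM from its mean over the libraries. The correlation was 0.36 in knockout 13, -0.53 in floxed 8 and between -0.13 and 0.16 in the other libraries. Between transcript length and the log2 fold change the rank correlation was 0.22. Secretory granule genes were called lower (21 genes, 19 with negative values, median -0.12, adjusted p = 0.0395; 0.685 with an estimated correlation), again with 0 members passing by either adjustment. The vesicle GTPase gene Rab3a had the smallest p of the list at a log2 fold change of -0.41, the granule protein gene Scg2 was at -0.47, and Chgb, at 813 CPM in floxed 8 and no more than 26.8 CPM elsewhere, was at -3.51. That call ended without knockout 12, floxed 8 or floxed 19 (medians -0.08, -0.14 and -0.10, adjusted p = 0.183, 0.0786 and 0.0603), without both knockout 12 and floxed 8 (0.315) and with the acinar covariate (0.208).

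The remaining lists were not called by camera. Cholesterol synthesis had a median log2 fold change of -0.15 (adjusted p = 0.0578) with Fdps at -0.32 and Hmgcs1 at 0.48, fatty acid synthesis one of -0.12 (adjusted p = 0.0962), and both were called lower without floxed 8 (adjusted p = 0.00593 and 0.00293), without both knockout 12 and floxed 8 (0.00812 and 0.00496), with limma-voom with quality weights (0.00533 and 0.00724) and with the length correction (0.0455 for both). Cholesterol synthesis was also called lower with plain limma-voom (0.0440). In these 2 lists 0 members passed when adjusted over the list alone. Cell cycle genes had a median of 0.20 (adjusted p = 0.0690; called higher without knockout 13 at 0.00928, with library totals at 0.0469, with the immediate early covariate at 0.0247 and with the length correction at 0.0379), with the replication genes Mcm4 and Pcna passing when adjusted over the list alone. Interferon response genes had a median of -0.06 (adjusted p = 0.0767; called lower without floxed 19 at 0.00116, with the acinar covariate at 0.00397 and with the immediate early covariate at 5.0e-05), with the antiviral gene Rsad2, at 1.61 ± 0.302 CPM in knockout and 4.19 ± 1.04 CPM in floxed islets (SD, n = 3 each), passing when adjusted over the list alone. Oxidative stress genes had a median of 0.00448 (adjusted p = 0.430; called higher without floxed 8 at 0.00139 and without both knockout 12 and floxed 8 at 0.00138, and lower with the immediate early covariate at 0.0247), with Txnip and catalase, Cat, passing when adjusted over the list alone and Hmox1 at a log2 fold change of 1.34. The 7 tested genes of beta cell dedifferentiation had a median of -0.20 (adjusted p = 0.430) and 0 passing. In none of these 6 lists did a member pass over all genes tested.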

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

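The immediate early covariate, the length correction and the joint removal of knockout 12 and floxed 8 were chosen after seeing the data. Counts of changed genes depended on the tool and on single libraries: against 45, DESeq2 called 567 (431 higher, 136 lower), limma-voom with quality weights 1733, the immediate early covariate 75 (42 higher, 33 lower), the acinar covariate 0 (973 at an unadjusted p below 0.05) and a threshold of 0.10 342. With single libraries left out the count ran from 0 (without knockout 11 or 13, where 1861 and 1204 genes had an unadjusted p below 0.05) to 1584 (without floxed 8), and it was 1393 without both knockout 12 and floxed 8. DESeq2 and the fit without floxed 8 each called all of the 45 genes; the cause of the larger counts was not tested. No filter, the 1 CPM filter, RLE scaling, library totals, plain limma-voom, no robust fit, removal of acinar genes and the length correction kept the count within 1.5 times.

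Thbs1 kept its direction in all 19 alternatives. It passed with DESeq2 (log2 fold change 2.01, adjusted p = 2.8e-04), with limma-voom with quality weights (1.85, adjusted p = 0.0435), without knockout 12 (1.51), and without both knockout 12 and floxed 8 (1.46, adjusted p = 0.00193); leaving out single libraries gave 1.51 to 2.25. Ern1 passed in 0 alternatives and changed sign with library totals (-0.0653), quality weights (-0.0736), the length correction (-0.0385) and without both libraries (-0.0409), with -0.13 to 0.15 when single libraries were left out. The covariates moved Ern1 most, to 0.48 with the acinar level (edgeR adjusted p = 0.641) and 0.56 with the immediate early level (unadjusted p = 0.00992, edgeR adjusted p = 0.128). Against 11 called lists, 17 were called at a threshold of 0.10, and 0 with an estimated correlation or with fry. Without floxed 8, fry called lists such as immediate early and heat shock genes (adjusted p = 0.00114), endothelial markers (0.00575) and anti-angiogenic factors (0.0396). It also called lists that camera had not called with all 6 libraries. Among these were fatty acid synthesis (fry adjusted p = 0.00114), hypoxia response and oxidative stress (0.00575 each), cholesterol synthesis (0.0244) and pro-angiogenic factors (0.0323). The acinar covariate called 6 lists, of which oxidative phosphorylation alone had been called in the same direction, PERK-ATF4 targets turned downward, and the alpha cell, delta and PP cell, interferon and basement membrane lists were new; the cause was not tested.

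Signs also changed among other named genes, most often with a covariate. With the acinar covariate Cdh5 was at 0.34, Kdr at 0.62 and Tapbp at 0.0368, and genes of stress and inflammation turned negative: Hsph1 -0.0571, Cxcl1 -1.11, Cxcl10 -1.55, Btg2 -0.00213, Ier3 -0.200, Tnfaip3 -0.16 and Ddit3 -0.26; with the immediate early covariate Cdh5 was at 0.44, Kdr at 0.52, Vegfa at -0.13, Cxcl10 at -0.74 and Scg2 at 0.20; with quality weights Gcg was at 0.13 and Chgb at 0.67. Without both libraries Gcg was at 0.22, Col3a1 at -0.42, Col1a1 at -0.57, Col6a1 at -0.19, Lum at -0.00591 and Chgb at 0.98. Leaving out single libraries gave Gcg -0.41 to 0.23, Kdr -0.37 to 0.0333, Lum -0.21 to 3.13, Col3a1 -0.34 to 2.36, Col1a1 -0.76 to 2.79, Col6a1 -0.24 to 1.79 and Chgb -4.08 to 1.06. Log2 ratios of marker shares ran from -0.64 to 2.30 for fibroblasts, -0.42 to 0.0646 for alpha cells and -0.49 to 0.52 for macrophages, with the sign set by knockout 12 or, for alpha cells, floxed 8. No paired or blocked analysis was possible because no litter, batch or pairing is given in the sources used here. At about 19 counts per CPM, genes near 1 CPM such as Cxcl1 rest on few reads.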

Other observations

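All tests in this part, and the genes outside the fixed rule named here, were chosen after the data were seen. Among 623 Reactome sets, camera called 18 higher and 12 lower in knockout islets, and 0 with an estimated correlation (smallest adjusted p = 0.882). These sets overlap, so the counts are not counts of separate findings. Many of the higher sets were PI3K signalling sets led by the same genes, Pik3r1 (log2 fold change 0.74, edgeR adjusted p = 0.0339) and Hbegf (1.62, 0.0683). A circadian clock set was listed more than once. Genes that build the lipid-linked precursor of N-glycans had a median log2 fold change of -0.14, with 43 of 53 below 0 (adjusted p = 0.00150; 0.882 with an estimated correlation). The mannosyltransferase gene Alg3 was at -0.53 and Dpagt1, the enzyme of the initial step, at -0.46 (edgeR adjusted p = 0.125 and 0.143). The circadian clock set was higher, with 17 of 21 genes above 0 and a median of 0.30 (adjusted p = 0.00181; 0.882 with an estimated correlation). Its leading members were the clock repressor genes Per2 (0.79) and Bhlhe40 (1.27) and the nuclear receptor gene Rora (0.50), with edgeR adjusted p from 0.126 to 0.143. Respiratory electron transport genes had a median of -0.14, with 61 of 65 below 0 (camera adjusted p = 2.3e-04, or 0.972 with an estimated correlation), and without floxed 8 that median was -0.05. The length correction, which ended the call of the fixed oxidative phosphorylation list, was not run on the Reactome sets. The set with the smallest p, activation of matrix metalloproteinases (19 genes, median 1.85), was led by trypsinogen and kallikrein genes of the exocrine pancreas, and 4 of its members are in the acinar list.

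Single libraries held large differences of their own, and the genes in this paragraph were picked after their values were seen. Chgb, the granule protein chromogranin B, was at 813 CPM in floxed 8 and between 11.4 and 26.8 CPM in the other 5 libraries, while Chga, chromogranin A, lay between 7413 and 9274 CPM in all 6. Without floxed 8, Chgb was higher in knockout islets (log2 fold change 1.06, edgeR adjusted p = 2.7e-04). The replication gene Mcm6 was at 2.08 CPM in floxed 8 and between 8.21 and 9.82 CPM elsewhere, and Stmn2 at 9.95 CPM against 2.34 to 3.41 CPM. Knockout 12 held 51 genes at least 2-fold above all 5 other libraries, among them Mmp2, Col1a1, Col3a1 and Thbs1, and floxed 18 held 52 genes at least 2-fold below all others, many of them acinar enzyme genes.

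Higher Thbs1 in knockout islets has several possible sources. Stromal cells in knockout 12, the library with the most collagen transcripts, are argued against as the whole source, since the log2 fold change without that library was 1.51 with a standard error of 0.15. Acinar carry-over stays open: with the acinar level as a covariate the group effect was 1.79 with an interval from -0.96 to 4.53, because acinar levels differed between the groups. An acute stress state also stays open (2.15 with the immediate early covariate, interval from -0.55 to 4.85), although floxed 8, with stress genes near the knockout level, had 27.8 CPM of Thbs1. Loss of endothelial IRE1α, which the design names, may be the source and was not tested apart from these.

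Lower endothelial markers may follow a tissue state. With the mean of the immediate early list as a covariate, the group effect on the endothelial list mean was 0.0734 log2 units (interval from -0.13 to 0.27), against -0.30 without it, and this rests largely on floxed 8, which had low endothelial markers and high stress genes. Dilution by other cells stays open, since the difference between the endothelial and beta cell list means was -0.20 between groups with an interval from -0.58 to 0.19. An effect of the deletion on islet vessels stays open as well, since the deletion and the tissue state overlap in 5 of the 6 libraries.

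Stress genes were high in the 3 knockout libraries and in floxed 8. On a scale from floxed 18 and 19 (0) to the knockout libraries (1), floxed 8 lay at 0.832 for immediate early and heat shock genes, a value that restates the pattern and rests on 1 library, so the deletion as the source stays open. Of 344 genes that were called and changed by at least 1 log2 unit without floxed 8, 315 were higher and 29 lower in knockout. Of the 344, 81 (23.6%) placed floxed 8 nearer to the other floxed libraries. This share lay between the bounds set, after the data were seen, for a wrong label and for a right one. Stress and acinar genes are among the 344, so the share cannot part that tissue state from the label. A wrong label for that animal stays open. Single genes ran with its label, with 27.8 CPM of Thbs1 (75.5 to 189 in knockout), 4.51 CPM of Cartpt (0.228 to 0.390) and 11.4 CPM of Rec8 (2.84 to 3.20), of which Cartpt and Rec8 were called with floxed 8 counted as floxed. A difference in handling, such as the delay before lysis, stays open too, since no handling day is given in the sources used here. All 15 immediate early and heat shock genes placed floxed 8 nearer to knockout, which restates the pattern and does not bear on its source.

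Of the called genes, 3 (Cartpt, Enc1 and Pik3r1) lay within 4.53 Mb on chromosome 13, and 34.7% of 10000 random draws of 44 genes held as many within 5 Mb, so this grouping did not exceed chance. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 45 genes and the highest of the others 0, so 1 split reached the real count. For gene lists the real split called 11 and the highest of the others 16, and 5 of the 10 splits called at least 11.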
